A study of Mus musculus with 2 samples.

How the data were processed

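The series measured polyadenylated RNA of the limb of mouse embryos at embryonic day 14.5 in 2 libraries of 1 group. The labels give each library its biological replicate number, which is used here as the name of the library. Each library came with a table of gene values, a table of transcript values and a text file that lists the library's files. Per these text files, the tables were made on the mm10 genome build with the GENCODE M4 annotation from alignments to the transcriptome. The quantification tool, the aligner and the strand setting are not given in the sources used here. Per the labels, the RNA was longer than 200 nucleotides, and a spike-in reference is named.

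The deposited tables hold, per the file headers, expected counts (the estimated number of reads per gene or transcript, which need not be whole), TPM and FPKM. TPM are scaled to the same sum over all rows in each library, and the rows include phage phiX174, ERCC spike-ins and 26248 short rows named by number. FPKM, per the file headers, are scaled by effective length and by the number of counted fragments. The effective length lay 35 nucleotides below the length. The deposited tables also hold posterior mean counts with their SD as other values, and posterior mean TPM, treated here as a score. A numbered short row without reads held 27.64 in replicate 1 and 27.85 in replicate 2, so rows without reads can hold a value there. The transcript tables hold, per the file headers, the percent of a gene's expression given to each transcript. The replicates were quantified separately.

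The gene tables have 69691 rows, of which 43346 are mouse genes, and those of transcripts have 129984 rows. Gene symbols, biotypes and coordinates were taken from GENCODE M21 on the same build by gene identifier; 42462 mouse rows matched and 884 did not. Of the 357 list genes 356 matched; Ahsp did not. The 32 lists of cell types and programmes, the rule for named genes, the tests and most alternatives were fixed before the data were examined. The rule took the 20 genes of highest mean TPM, the 4 highest members of each list with all limb type, sex-linked and Hox genes, 10 coding genes on each side for the difference between the libraries (mean of at least 5 TPM, past the test, ordered by the median-centred log2 ratio of TPM with a pseudocount of 0.1), and for isoforms 12 fixed genes and the 10 highest list genes whose leading transcript differed.

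Because the labels give 1 group and no contrast, levels are given as the mean and SD over the libraries, and no test of conditions was made. The library totals on mouse genes were 27446 and 19200 expected counts, and the phiX174 row took 85.8% and 89.1% of all counts. This depth limits every value, since 116 genes in replicate 1 and 75 in replicate 2 reached 20 counts. For that reason counts stand beside TPM, and a gene was called detected at an expected count of 0.5 or more. The comparison of each list's detected members with 10000 random lists of protein-coding genes, drawn within 20 bins of transcript length, was chosen after the depth was seen. For shares, exact (Clopper-Pearson) 95% binomial intervals are given.

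The libraries were compared gene by gene with a two-sided exact binomial test on expected counts rounded to whole numbers. The success share came from library sizes scaled by the trimmed mean of M values (TMM) in edgeR 4.0.16 over mouse genes, genes had at least 20 counts over both libraries, and p-values were adjusted by Benjamini and Hochberg at 0.05. The scaled size of replicate 2 relative to replicate 1 was 0.828 by TMM, 0.70 by summed counts and 1 by the size factors of DESeq2 1.42.0. Folds of genes at 0 in a library are lower bounds against 3 counts in that library. The median log2 ratio of each list (TPM with a pseudocount of 0.1, centred on the median gene, whose shift was -0.79) was placed among 10000 random lists matched on mean TPM in 20 bins. Leading transcripts were compared for genes with at least 2 transcripts and a mean of 5 TPM.

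Tested on counts simulated for the comparison of replicate 2 with replicate 1, with 284 genes tested, the binomial test called 26.1% of genes changed 2-fold in the right direction, 67.6% of those changed 4-fold and 94.9% of those changed 8-fold, and 1.06% of unchanged genes. Of 200 unchanged random lists over 3000 simulated genes, 3% fell outside the central 95%.

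Near-identical copies were found by aligning transcripts with blastn 2.17.0 (at least 95% identity over at least 100 nucleotides, and for nuclear genes at least 50% of the shorter transcript). Genes with exons on opposite strands were paired with bedtools 2.31.1 (at least 50 nucleotides of overlap). Other steps used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Matplotlib 3.10.9 and R 4.3.3. Alternatives covered the minimum level, the pseudocount, the scaling, the authors' posterior estimates, FPKM, what TPM are relative to, gene length, and leaving out each library. Alternatives added after the data were seen used count thresholds, all rows of the TPM and the summing of mitochondrial messengers with their nuclear copies. The signal tracks were not analysed here, except for their sizes in the text files.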

Results

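RNA of the embryonic mouse limb was measured by sequencing of polyadenylated RNA at embryonic day 14.5, a stage at which cartilage, tendon, muscle and skin form in the limb. The series held 1 group of 2 libraries, replicate 1 and replicate 2, which the labels number as biological replicates of the B6NCrl strain. One label of each sample speaks of a single mouse and another of pooled males and females, so the number of embryos behind each library is open, and differences between the libraries may be technical. The labels name no fore- or hindlimb and no contrast, so the values below describe the tissue and the spread between the libraries. All means ± SD are over n = 2 libraries.

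The deposited gene tables held 193982 expected counts in replicate 1 and 176608 in replicate 2. Most of these lay on the row of the bacteriophage phiX174, a genome added to sequencing runs as a control: 166481 counts in replicate 1 (85.8%, exact 95% binomial confidence interval 85.7 to 86.0) and 157315 in replicate 2 (89.1%, 88.9 to 89.2), or 87.4% ± 2.30 (SD). Mouse genes received 27446 and 19200 expected counts. The 96 rows of the ERCC spike-in RNAs had 0 counts in both libraries. A count of 0 in a gene allows up to 0.0109% of the mouse counts in replicate 1 and 0.0156% in replicate 2 (3 counts of the total). Intervals and floors cover counting error only.

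**Figure D1:**
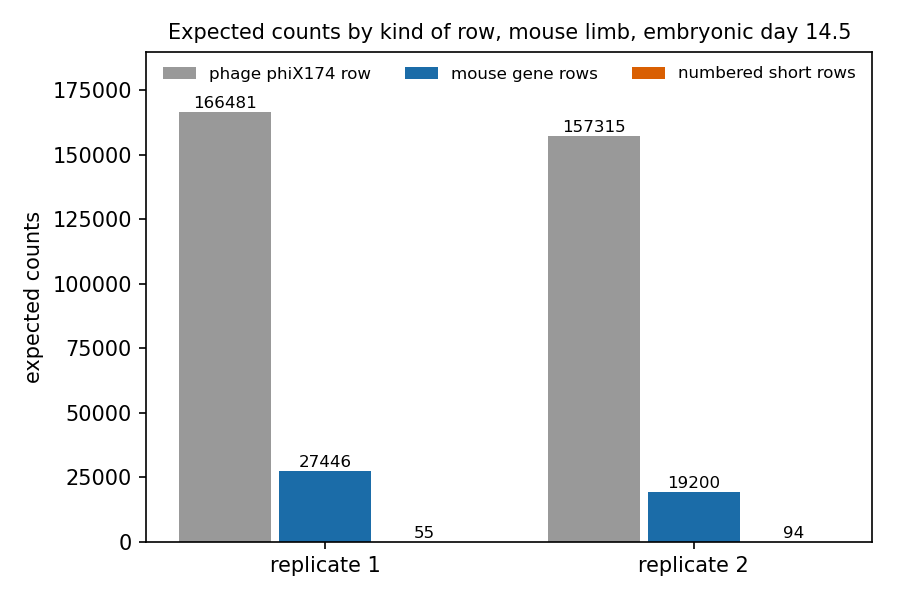
Expected counts (y axis) per library (x axis) on the phiX174 row, on mouse gene rows and on the numbered short rows; each bar is 1 library. The mouse rows hold 27446 and 19200 counts, beside 166481 and 157315 on the phage row.

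At this depth 6766 genes had a count in replicate 1 and 5484 in replicate 2, 3312 genes had a count in both, and 8938 had a count in either (a count being an expected count of at least 0.5). A mean of at least 1 TPM, the authors' transcript abundance normalised for length and depth, was reached by 8972 genes, by 3326 genes in each library, and by 5514 when replicate 1 was left out. A single count was worth a median of 6.67 TPM in replicate 1 and 8.3 TPM in replicate 2 over protein-coding genes, so a single count in one library already exceeded this threshold for most genes. At least 3 counts in each library were found for 770 genes. Protein-coding genes took 77.5% ± 0.949 (SD) of the mouse counts, the mitochondrial chromosome 7.70% ± 0.482 and pseudogenes 5.96% ± 1.59.

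The 20 genes of highest mean TPM were led by RNAs of the mitochondrion and by non-coding RNAs. They took 30.1% ± 5.43 (SD) of the TPM on mouse genes; within protein-coding genes the 20 highest took 16.0%. Rn7sk, the small nuclear RNA that restrains transcription elongation (chromosome 9, 78175303 to 78175633), came first with 27114 TPM ± 38243, from 864 counts in replicate 1 and 1 in replicate 2. The row ENSMUSG00000045999, which the annotation used here does not name, had 1913 and 1411 counts, 7.16% ± 0.269 of the mouse counts. The mitochondrial ribosomal RNAs mt-Rnr1 (7783 TPM ± 3710) and mt-Rnr2 (4360 TPM ± 262) followed, with the messengers mt-Co3 (6038 TPM ± 8539), mt-Co1 (4154 TPM ± 918), mt-Cytb (3631 TPM ± 2708), mt-Atp6 (2526 TPM ± 3567) and mt-Nd4 (1966 TPM ± 449). The nuclear copies of mitochondrial sequence Gm28438, Gm29216, Gm10925, Gm10222, Gm28437 and Gm28661 ranked among them, and 4 of these 6 align to a mitochondrial messenger at 100% identity, so their reads cannot be assigned with certainty. Among other coding genes, the translation elongation factor Eef1a1 had 3506 TPM ± 1416 (113 and 110 counts), the leucyl-tRNA synthetase Lars2 1432 TPM ± 845 (173 and 365 counts) and Tpt1 1298 TPM ± 1628 (7 and 63 counts). The list was completed by Gm42418 (196 and 241 counts) and Gm26445 (0 and 8.35 counts). The annotation used here classes them as a long non-coding RNA and a microRNA. The origin of the reads on these rows was not tested.

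Transcripts of the limb mesenchyme and of cartilage were present in both libraries. The cartilage list had counts for 13 of 18 members, with 33 counts in replicate 1 and 37 in replicate 2. The fibrillar and fibril-associated collagens Col11a1 (46.1 TPM ± 49.99, 2 and 10 counts), Col9a1 (41.7 TPM ± 19.1, 9 and 5 counts) and Col2a1 (28.8 TPM ± 40.7, 0 and 13 counts) led it, with the chondrogenic factor Sox9 (24.4 TPM ± 2.44, 5 counts in each library). Its number of members with a count lay at percentile 97.9 of 10000 random lists of protein-coding genes matched on transcript length. Hypertrophic cartilage markers were sparse, with 2 of 9 members detected (percentile 24.15): Runx3 had 1 count in each library and the parathyroid hormone receptor Pth1r 0 and 3. The osteoblast list had 4 of 14 members with counts, at percentile 18.2 of the random lists. Most of its counts lay on the type I collagen genes Col1a2 (82.5 TPM ± 45.8, 13 and 27 counts) and Col1a1 (18.99 TPM ± 9.05, 4 and 7 counts). Runx2 had 26.8 TPM ± 37.9 (0 and 2 counts) and Phex 1 and 0 counts. The other members, among them Sp7, Bglap, Satb2, Dlx5 and Dmp1, had 0 counts.

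The joint list had 6 of 10 members with counts, among them the joint interzone factor Gdf5 (29.7 TPM ± 15.5, 5 and 2 counts), Osr1 (20.2 TPM ± 2.02, 2 counts in each), Trps1 (8 and 2 counts) and Wnt16 (0 and 1). The tendon list also had 6 of 10, again inside that range (percentile 83.0), with Scx, Egr2, Thbs4 and Col14a1 at 0 in both libraries. Its leading members were the transcription factor Mkx (75.4 TPM ± 38.5, 6 and 1 counts), keratocan, Kera (49.9 TPM ± 39.0, 8 and 2 counts), the fibril-associated collagen Col12a1 (30.7 TPM ± 17.2, 8 and 22 counts) and tenomodulin, Tnmd (2 and 0 counts). Connective tissue was the best covered mesenchymal list, with counts for 10 of 10 members, 110 in replicate 1 and 98 in replicate 2, at percentile 99.9 of the random lists. Fibronectin, Fn1, had 201 TPM ± 26.3 (34 and 39 counts), periostin, Postn, 91.8 TPM ± 37.0 (12 and 5), the growth factor receptor Pdgfra 60.5 TPM ± 21.1 (16 and 23) and the type III collagen gene Col3a1 56.0 TPM ± 30.0 (23 and 9).

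Muscle fibre genes had counts for 11 of 23 members, 24.0 and 29 in total, inside the range of the random lists (percentile 87.2). The cardiac actin gene Actc1, which embryonic skeletal muscle also uses, had 0 and 5 counts, the regulatory light chain Mylpf 0 and 3, Myl1 0 and 2, and the slow troponin Tnnt1 1 in each. These were the highest members by TPM. By counts the list was led by Ttn (14 and 8), Myh3 (4 in each) and Neb (3 and 4), counted in both libraries. Of the myogenic regulators 3 of 15 had counts, Cdh15 (0 and 2), Mef2c (4 and 0) and Six1 (1 and 0). The list lay at percentile 3.07 of the random lists.

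Basal epidermis stood above the random lists in members with a count in either library, with 9 of 12 (percentile 99.7). Of these, 2 had a count in both libraries, and each of the others had 1 count in a single library. Krt14, Krt8 and Krt18 had 0 counts in both. Desmoplakin, Dsp, had 25.1 TPM ± 15.1 (6 and 8 counts) and the basal keratin Krt5 23.5 TPM ± 8.87 (2 and 3 counts), with Krt17 at 0 and 1 counts and Sfn at 1 and 0. Of the differentiating epidermis list 2 of 10 members had counts, Krt1 and Krt10, each with 0 and 1.

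Erythroid transcripts had 145 counts in replicate 1 and 62 in replicate 2, over 12 of 14 matched members (percentile 100 of the random lists). The globin genes Hba-a2 (1112 TPM ± 1035), Hbb-bs (835 TPM ± 638), Hbb-bt (662 TPM ± 235) and Hbb-y (416 TPM ± 250) led the list. Near-identical globin paralogs share reads, so their sums are firmer than single members. Adult globins had 115 counts against 20 of the embryonic globins in replicate 1, and 48 against 8 in replicate 2. By summed TPM, the ratio of adult to embryonic globin was 6.25 ± 0.0307 (SD). From the counts alone it was 5.75 in replicate 1 (exact 95% interval 3.56 to 9.76) and 6 in replicate 2 (2.81 to 14.7), so counting error exceeded the spread between the libraries.

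Other cell types were thinly covered. The endothelial list had 6 of 13 members with counts, 1 in replicate 1 and 9 in replicate 2, led by Emcn (0 and 2), Egfl7 (0 and 1), the vascular cadherin Cdh5 (0 and 3) and Sox18 (0 and 1). The mural list had 4 of 8, with Pdgfrb at 1 and 7 counts, Acta2 at 1 in each, and Rgs5 and Cspg4 at 0 and 1. Macrophage genes had 4 of 14, each with 1 count in a single library (Pf4, Ptprc, C1qc and Cx3cr1). Osteoclast genes had 1 of 7, Ctsk with 1 and 0 counts. Schwann cell genes had 5 of 10, with S100b at 1 and 0 counts, Mpz at 0 and 1, Erbb3 at 2 and 0 and Plp1 at 1 and 0. No melanocyte gene (0 of 5) had a count in either library.

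Limb patterning genes had counts for 23 of 35 members, 77 in replicate 1 and 48.0 in replicate 2 (percentile 97.6 of the random lists). The hedgehog effector Gli3 had 67.0 TPM ± 64.0 (4 and 9 counts), the mesenchymal factors Twist1 66.3 TPM ± 55.6 (9 and 2) and Prrx1 51.9 TPM ± 59.4 (21 and 3), and the signal Wnt5a 62.8 TPM ± 38.6 (3 and 6). Of the limb type factors, the forelimb gene Tbx5 had 3 and 1 counts and the hindlimb gene Pitx1 3 and 0, while Tbx4 and Isl1 had 0 in both. A ratio of Tbx5 to Tbx4 was not computed, because both genes lay at or under the floor of 3 counts in each library.

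The Hox genes with counts came almost all from the 5′ ends of the Hoxa and Hoxd clusters. Hoxd13, which patterns the digits (chromosome 2), had 84.5 TPM ± 94.8 (20 and 2 counts), Hoxd10 0 and 2 counts, Hoxd11 1 and 2, and Hoxd12 2 and 1. Hoxa13 had 36.4 TPM ± 40.4 (1 and 5 counts), Hoxa9 2 and 1 counts, Hoxa10 1 and 2, Hoxa11 0 and 0.49, and Hoxa3 1 and 0. Groups 9 to 13 made up 98.4% ± 2.24 (SD) of the TPM of the Hoxa and Hoxd clusters, from 27 of 28 counts in replicate 1 (exact 95% interval 81.7 to 99.9%) and 15 of 15 in replicate 2 (78.2 to 100%). With the posterior mean TPM of the authors' tables, in which rows without reads can hold values above 0, the share was 53.9%. The other Hoxa genes (Hoxa1, Hoxa2, Hoxa4, Hoxa5, Hoxa6 and Hoxa7) and Hoxd1, Hoxd3, Hoxd4, Hoxd8 and Hoxd9 had 0 counts. Of the Hoxc genes Hoxc12 had 2 and 0 counts and Hoxc4, Hoxc5, Hoxc6, Hoxc8, Hoxc9, Hoxc10, Hoxc11 and Hoxc13 had 0. The Hoxb cluster had 0 of 10 members with a count (Hoxb1 to Hoxb9 and Hoxb13), below the random lists at percentile 0.72.

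Growth and proliferation genes were among the best covered. Imprinted growth genes had counts for 10 of 10 members in both libraries, 210 and 197 in total (percentile 99.9). They included the long non-coding RNA H19 (1032 TPM ± 321, 32 and 91 counts), the fetal growth factor Igf2 (783 TPM ± 574, 92 and 27), Meg3 (449 TPM ± 341, 35.9 and 9) and Mest (137 TPM ± 42.9, 14.5 and 19). Cell cycle genes had counts for 13 of 16 members, 50 and 39 in total (percentile 99.9), led by TPM by the mitotic kinase Cdk1 (77.7 TPM ± 50.3, 1 and 3 counts), Pcna (59.9 TPM ± 30.1, 4 and 1), Rrm2 (59.4 TPM ± 37.6, 3 in each) and Mcm6 (52.0 TPM ± 41.0, 4 and 3). By counts Mki67 (20 and 15) and Top2a (13 and 2) led this list. Hypoxia response genes had 7 of 10 (percentile 99.2), of which 2 had a count in both libraries. Lactate dehydrogenase Ldha had 108 TPM ± 45.4 (4 counts in each), and Pgk1 had 3 and 0 counts. Pdk1 had 22.7 TPM ± 0.346 (5 and 3) and Vegfa 4 and 0 counts, while Adm, Ankrd37 and Egln3 had 0 in both. The random lists were matched on transcript length, not on level, so this percentile alone does not show a low-oxygen response. The immediate early list had 2 of 11, Jun (4 and 0 counts) and Dusp1 (1 and 0).

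Lists of tissues outside the limb were included as a background. Liver genes had 27 and 5 counts over 4 of 8 members (percentile 93.6), mostly from alpha-fetoprotein, Afp (82.8 TPM ± 87.6, 16 and 2 counts) and albumin, Alb (52.2 TPM ± 43.7, 9 and 2), with Apoa2 at 1 in each and Apoa1 at 1 and 0. Forebrain genes had 1 of 6, Neurod6 with 3 and 0 counts. Heart (0 of 5) and lung and gut (0 of 5) had none. Among sex-linked genes, the X-inactivation RNA Xist had 84.8 TPM ± 56.8 (32.4 and 37 counts), and the Y-linked genes Ddx3y (2 and 1), Kdm5d (0 and 2) and Eif2s3y (1 and 0) summed to 3 counts in each library, while Uty had 0.

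**Figure D2:**
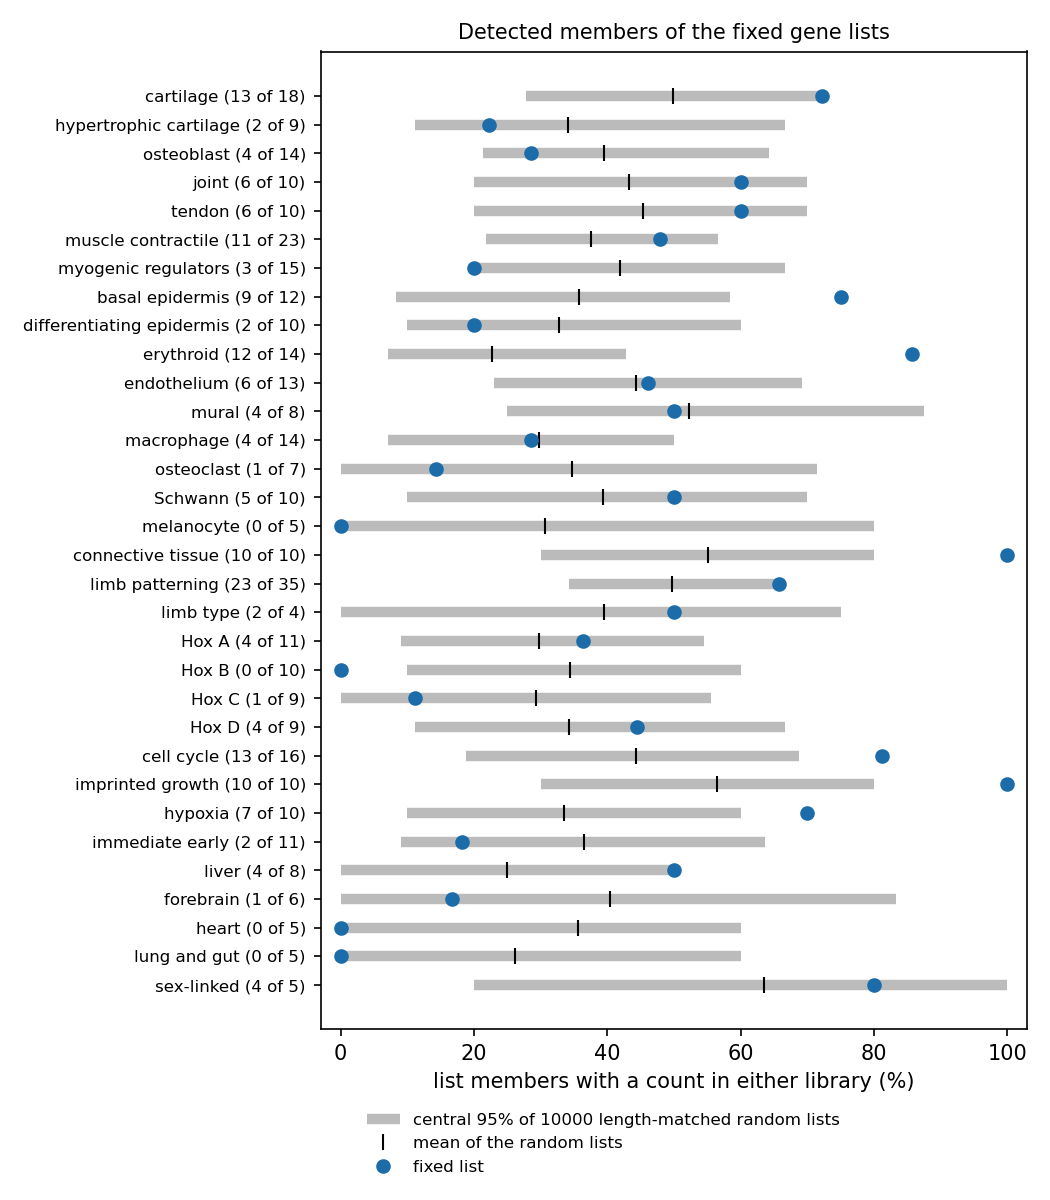
Percent of each fixed list's members with a count in either library (x axis, dots; the y axis names each list with its detected and matched members), beside the mean (tick) and the central 95% (bar) of 10000 random lists matched on transcript length. The erythroid, connective tissue, imprinted growth, cell cycle, basal epidermis and hypoxia lists lie to the right of their bars, and Hox B to the left.

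Across all lists, 174 of the 356 matched genes reached a mean of 1 TPM. A count was found for 48.6% of the list genes, beside 36.9% of all protein-coding genes. In detection, 6 of the 32 lists lay above the central 95% of the random lists and 1 below; the cartilage, limb patterning and liver lists lay on the upper limit. These percentiles describe the 2 libraries and are not p-values.

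The replicates were then compared with each other, to see whether they differed by more than the sampling of reads. They did. Of 240 genes with at least 20 counts over both libraries, 149 (62.1%) passed the exact binomial test (two-sided, Benjamini-Hochberg threshold 0.05), 56 higher in replicate 2 and 93 higher in replicate 1. This split depended on the scaling. It was 70 and 82 with summed counts, and 52 and 105 with DESeq2 size factors. Of these 240 genes, 40 had counts in a single library only. The median size of the difference over the 240 genes was 1.64 on the log2 scale, or 3.12-fold. Among the list genes 20 could be tested and 9 passed, both over all genes tested and adjusted over the list alone. Hba-a2, Hbb-bs, Igf2, Meg3, Hoxd13 and Prrx1 were higher in replicate 1. Summed with its near-identical paralog Hbb-bt, Hbb-bs had 61 and 34 counts (log2 ratio -0.56, unadjusted exact binomial p = 0.0642), so its call rests on how reads were assigned; Hba-a1 and Hba-a2 together had 54 and 14 counts (log2 ratio -1.64). H19, Col12a1 and Col1a2 were higher in replicate 2. H19 (log2 ratio 1.77, adjusted exact binomial p = 9.65e-10) and Igf2 (log2 ratio -1.48, adjusted exact binomial p = 1.50e-06), neighbours on chromosome 7, differed in opposite directions. The test compares these 2 libraries, not conditions.

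**Figure D3:**
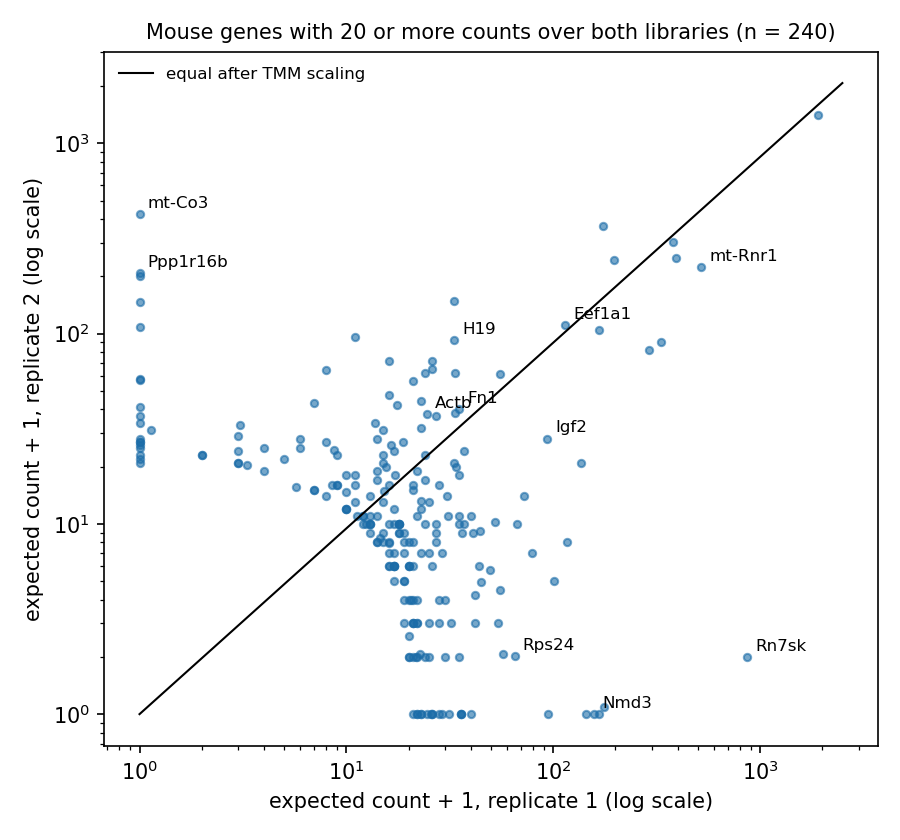
Expected count + 1 of replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale) for the 240 mouse genes with at least 20 counts over both; each point is a gene and the line marks equal levels after scaling by trimmed means. Points on the left edge and along the bottom are genes counted in a single library, such as mt-Co3 (0 and 423 counts) and Nmd3 (157 and 0).

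The correlation of the libraries across genes was low. Over the 8972 genes at a mean of 1 TPM, Pearson's r of log2(TPM + 1) was -0.170 and Spearman's rho -0.165. Genes are not independent replicates, and with few counts per gene a filter on the mean lowers r. On log2(count + 1), r over the same genes was 0.170, where random splits of each gene's counts between the libraries gave 0.511. For the 240 genes with at least 20 counts, r was -0.188 and random splits gave 0.914 (means of 100 splits). The correlation also turned positive by TPM without a filter, at 0.464, where most genes are at 0 in both, and with posterior mean TPM, at 0.907. The median absolute log2 ratio over genes at 1 TPM was 5.65 (pseudocount 0.1 TPM, 50.4-fold), set by genes at 0 in one of the libraries. It was 6.04 for TPM scaled by trimmed means, and 1.31 for scaled counts with a pseudocount of 0.5 count, where 1 count stands against 0. Of genes with 3 to 5 counts, 61.1% were seen in both libraries, where random sampling would give 81.9%, and of those with at least 51 counts 80%, where it would give 100%.

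Among coding genes past the test at a mean of 5 TPM, ordered by the TPM ratio with a pseudocount of 0.1, the 10 genes of each side were counted in a single library, apart from Tnfrsf10b. This order favours genes at 0: Rn7sk, which is not coding (864 and 1 counts), and mt-Atp6 (175.77 and 0.09 counts) are not among them. Higher in replicate 2 were mt-Co3 (chromosome M, 8607 to 9390; 0 and 423 counts, at least 170-fold, adjusted exact binomial p = 4.13e-144), Ppp1r16b (chromosome 2, 158665398 to 158766334; 0 and 207 counts, at least 83.3-fold), Fbxl18 (chromosome 5, 142866946 to 142895421; 0 and 200 counts, at least 80.5-fold), Gdap1 (0 and 107 counts, at least 43.1-fold) and the histone variant gene H3f3a (0 and 57 counts, at least 22.9-fold). The other members of this side were Grap2 (0 and 40 counts), Fxr1 (0 and 33), Cntrl (0 and 27) and the ribosomal protein gene Rps29 (0 and 22), each at least 8.85-fold, and the death receptor gene Tnfrsf10b (1 and 22 counts, 26.6-fold, exact 95% interval 4.29 to 1096). Higher in replicate 1 were Nmd3, an export factor of the large ribosomal subunit (chromosome 3, 69721985 to 69756373; 157 and 0 counts, at least 43.3-fold, adjusted exact binomial p = 2.67e-40), Cpne9 (chromosome 6, 113282307 to 113305627; 143 and 0 counts, at least 39.5-fold) and Chpt1 (93 and 0 counts, at least 25.7-fold). Gm10717 (35 and 0 counts), the ferritin heavy chain Fth1 (34.9 and 0), Hnrnpf (27.9 and 0), Dynll1 (27 and 0), the neuronal enolase Eno2 (25 and 0), the cold-induced RNA-binding protein gene Rbm3 (25 and 0) and Gm10719 (21 and 0) were at least 5.80-fold higher. All lower bounds set the library at 0 to the floor of 3 counts. Coordinates are of mm10. Near-identical copies share sequence with mt-Co3, H3f3a, Rps29, Gm10717, Gm10719, Fth1, Dynll1, Hnrnpf, Rbm3, Chpt1 and Tnfrsf10b, so their single values are uncertain. With its copies H3f3a had 38.6 and 61 counts, Rbm3 25 and 3, Fth1 36 and 1, and Gm10717 and Gm10719 each 63 and 1. Adding copies left Dynll1, Chpt1 and Tnfrsf10b unchanged, and Rps29 (0 and 25 counts) and Hnrnpf (29 and 0) stayed in a single library. With its copy Gm28437, which is 100% identical over the aligned part, mt-Co3 had 166 and 423 counts, a log2 ratio of 1.62 (adjusted exact binomial p = 6.94e-37), so the bound of 170-fold holds for the counts as assigned only.

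The fixed lists showed few joint differences between the libraries. Of 14 lists with at least 5 members at 1 TPM, 1, the endothelial list (1 and 9 counts over 6 members), had a median ratio outside the central 95% of 10000 random lists matched on mean TPM, at percentile 99.6 toward replicate 2. With counts scaled by trimmed means and a pseudocount of 0.5 count none lay outside.

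Isoform values rested on few reads. Of 2411 genes with at least 2 transcripts, a mean of 5 TPM and a value in both libraries, 1678 (69.6%) had another leading transcript in each library, and 898 did by posterior mean TPM. For 1788 of the 2411 genes a library held 2 or fewer counts (up to 2.5), and the median leading share was 100% in both. Among 16 genes with at least 20 counts in each library, 13 still had another leader. Of the 12 genes fixed for isoforms 7 could be compared. Postn had the same leading transcript, with 53.4% of its TPM in replicate 1 and 55.3% in replicate 2. The leader changed in Fn1 (30.8% in replicate 1 and 47.8% in replicate 2 for their own leaders, 34 and 39 counts), Fgfr2 (73.7% and 54.8%, 6 and 7 counts), Fgfr1, Col11a1, Tpm1 and Sox6; Col2a1, Tnnt3, Tpm2, Runx2 and Pkm could not be compared. The 10 list genes of highest TPM with another leader were H19 (54.5% and 79.5%, 32 and 91 counts), Hbb-bs, Meg3, Fn1, Grb10, Xist, Cdk1, Gli3, Wnt5a and Pcna.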

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

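In this part, the tests of near-identical copies of nuclear genes and of cell content were planned before their results were seen; the other tests were chosen afterwards.

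Rows outside the mouse genes held counts above the limit that 0 counts allow. The phiX174 row took 85.8% of all expected counts in replicate 1 and 89.1% in replicate 2. The numbered short rows held 55 counts in replicate 1 and 93.9 in replicate 2.

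The first pattern weighed is the low number of mouse counts beside the phage control. Counting on the opposite strand is argued against by gene pairs with exons on opposite strands, where the long non-coding members held 9.96% of the counts (342 beside 3090 on the coding members). At single loci, Xist had 69.4 counts and its antisense partner Tsix 0, and Igf2 had 119 and Igf2os 1. Whether the libraries held few mouse reads stays open. The listed sizes of the signal tracks of uniquely aligned reads come to 2636 bytes per counted mouse read in replicate 1 and 3603 in replicate 2, but no table gives the bytes a read takes in such a track, and reads outside annotated transcripts would also fill it. An incomplete transcriptome alignment or a wrong paired-end setting behind the tables, which would change what every count means, was not tested, nor was a biological explanation.

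The second pattern is that mt-Co3 (0 and 423 counts) and mt-Atp6 (175.77 and 0.09 counts) were each counted in a single library. Reads shared with nuclear copies may account for these 2 messengers: adding Gm28437 (166 and 0 counts) and Gm10925 (32.2 and 148 counts), which match them at 100% identity, lowered their median absolute log2 ratio by 8.06, from 8.97 to 0.92. Both were picked for lying near 0 in a library, where any added counts lower the ratio, so the fall alone does not decide. Over the 9 messengers with a copy the median rose from 0.400 to 0.948, and over all 13 it went from 1.57 to 1.60. Of the 9, mt-Co2, mt-Nd3 and mt-Nd4l had at most 0.04 counts of their own in a library. Their ratios before adding copies therefore reflect the pseudocount and the scaling, and these medians do not decide. The log2 ratio also moved closer to equal, by less, in mt-Co1 (-0.386 to 0.218), mt-Nd4 (-0.400 to -0.173) and mt-Nd5 (1.16 to 0.948), while mt-Nd2 was unchanged. With the copies added mt-Atp6 was at a log2 ratio of -0.22, but mt-Co3 was still at 1.62 and past the exact binomial test (adjusted p = 6.94e-37), so shared reads leave a difference there. Of the 8 messengers with a copy and at least 20 counts, copies included, 5 were past the test: mt-Co1, mt-Co2, mt-Co3, mt-Nd3 and mt-Nd5. Of these, mt-Co2 and mt-Nd3 had too few counts of their own to be tested before. Also, mt-Co1 passed narrowly (adjusted exact binomial p = 0.048). For this count of messengers, p-values were adjusted over the tested messengers alone, while that of mt-Co3 above was adjusted over all tested genes. Adjusted over all tested genes, mt-Co1 may not pass. The messengers mt-Cytb (331 and 89 counts) and mt-Nd1 (15 and 71) have no such copy, so reads shared with the copies found here do not account for all differences. A different content of mitochondrial RNA is argued against as the only cause, because messengers went opposite ways. With copies added, log2 ratios were -3.67 in mt-Nd3 and -1.62 in mt-Cytb, but 2.48 in mt-Nd1 and 2.51 in mt-Co2. The 13 messengers summed with their copies had a log2 ratio of 0.25 (exact 95% interval 0.147 to 0.355), so a small shared shift is not excluded. That interval lay below the one of mt-Co3 with its copy (1.36 to 1.89). This comparison is weak, since mt-Co3 was picked for its ratio and is part of the sum. No other biological explanation was tested.

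The third pattern is that nuclear genes such as Ppp1r16b (0 and 207 counts) and Nmd3 (157 and 0) were counted mostly in a single library. Sampling of reads is argued against by a mean chi-square per nuclear gene of 23.0, where random sampling gives about 1. Reads shared with near-identical copies are argued against for the set. Of the 19 named nuclear genes 9 had no such copy, and with copies added 1 of the 19 (H3f3a) came within 2-fold. Gm10717 and Gm10719 had the same summed counts, so they may not be separate cases. The search required a minimum cover of the shorter transcript, so reads shared over shorter stretches were not tested. A different cell content of the libraries stays open: 1 of 14 fixed lists lay outside the random lists, which meets the bound set in advance against this explanation, but 58.8% of the members had 3 or fewer counts in both libraries, so the lists are too thinly covered to exclude it. Clumped reads, such as amplified copies of single fragments, were not tested.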

How the results depend on the processing

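Of the alternatives to the main results, 36 left the value within its limit, 25 moved it and 3 turned its sign; values without an SD were held to 10%, and counts to 1.5 times. The number of genes at a mean of 1 TPM (8972) was 3326 at 1 TPM in each library, 33353 with posterior mean TPM and 5514 to 6818 with a library left out. At least 3 counts in each library were held by 770 genes. The share of the 20 highest genes (30.1%) was 16.0% over protein-coding genes and 10.9% over all rows as deposited. The correlation (-0.170) was -0.310 with a pseudocount of 0.1, -0.00402 with 5, -0.298 at a mean of 5 TPM and -0.188 on counts over genes with 20 or more (unit and filter changed), and turned to 0.170 on counts over the same genes, 0.464 without a filter and 0.907 with posterior mean TPM, whose prior is shared by the libraries. The median absolute log2 ratio (5.65) was 2.83 with a pseudocount of 1, 0 without a filter, 6.44 at 5 TPM, and 1.31, 1.58 and 1.25 for counts with a pseudocount of 0.5 scaled by TMM, DESeq2 size factors and summed counts; the unit and pseudocount made this fall, since TPM with the main pseudocount gave 6.04, 6.06 and 6.01 under the same scalings. Genes past the exact binomial test (149 of 240) numbered 25 of the 28 with at least 100 counts, since fewer genes were tested, and 141 to 190 under the other settings. Of the 20 named genes of the difference, 19 had 0 counts in a library, which fixes their direction under most alternatives, so these tested the size: with near-identical copies added the log2 count ratio of mt-Co3 went from 9.998 to 1.62, of H3f3a from 7.12 to 0.92, of Rbm3 from -5.40 to -2.59 and of Fth1 from -5.88 to -4.33, and with posterior mean counts to 4.43, 4.35, -4.02 and -5.06. Lists outside the random range (1) numbered 0 with counts and a pseudocount of 0.5 scaled by TMM or DESeq2, and 1 with TPM scaled by TMM. The globin ratio (6.25) was 5.31 with posterior mean TPM and 5.88 on counts, within its counting interval. The distal Hox share (98.4%) was 53.9% with posterior mean TPM and 88.8% for groups 10 to 13. The share of the control rows, phiX174 with ERCC (all of it phiX174), was 87.4% of counts and 60.3% by TPM. Genes with another leading transcript (1678 of 2411) numbered 898 with posterior mean TPM. Beyond what the constructions above show, the cause was not tested. No alternative gave a ratio of Tbx5 to Tbx4, for want of counts. The 3-count floor of the libraries (0.0109% and 0.0156% of mouse counts) limits every list. No paired analysis was possible because there is 1 group. The count-based alternatives on detection, on the correlation and on all rows, the scaled TPM and the added copies were chosen after the data were seen.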

Other observations

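The tests in this part were chosen after the results were seen, as were the genes named here outside the lists. Of the genes that most cells use heavily, Eef1a1 was evenly covered (113 and 110 counts). Eef2, a translation elongation factor, was uneven, with 136 counts in replicate 1 and 20 in replicate 2. Beta-actin, Actb, had 23.4 and 36.8 counts. The glycolytic enzyme gene Gapdh had 1 and 0, too few to compare the libraries. The nuclear RNA Malat1 had 289 and 81 counts, and Igfbp5, an insulin-like growth factor binding protein gene, 10 and 95. The 82 ribosomal protein genes had 405 counts in replicate 1 and 352 in replicate 2, but single members went far apart: Rps24 had 64 and 1.02 counts, Rpl3 77.6 and 6, Rpl4 6 and 42, and Rpl28 2.05 and 32. Over the 10 of them with at least 20 counts the mean chi-square per gene was 24.4. Reads shared with processed pseudogenes were not tested for Rps24, Rpl3, Rpl4 and Rpl28, which leaves the single values uncertain.

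A hypothesis on sex was set beside the conflicting labels. It was prompted by the same sex-linked counts, so these counts do not test it independently. Both sexes in each library may account for the sex-linked counts: Xist had 32.4 and 37 counts, and the Y-linked genes summed to 3 counts in replicate 1 and 3 in replicate 2, the lower being 3 where a library of females alone would have 0. The Y-linked counts lie at the floor of 3, and misassigned reads of the X-linked homologs were not tested, so this stays a hypothesis.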
